A study of Mus musculus with 12 samples.

How the data were processed

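RNA was measured in 12 heart samples of male C57Bl/6J mice aged 12 weeks, 3 libraries in each of 4 groups. Mice received a diet without branched-chain amino acids (BCAA-free) or a control diet with them, from 4 days before surgery onward. Surgery was either sham or transverse aortic constriction (TAC), which narrows the aorta and raises the pressure load on the left ventricle, and hearts were taken 1 week later. The labels state Trizol extraction and selection of poly(A) RNA. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates were separate animals, so p-values measure only the spread between these samples, which may be technical.

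The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2 and DESeq2, the last without a version, and the builds GRCm38 and mm10. Their roles, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap, antisense partners and near-identical copies can therefore share reads. The authors deposited 4 tables, 1 for each pair of groups that differ in diet or surgery alone. Per the file headers, each table gives a signal per library (normalized read counts), a log2 fold change of the authors, and p-values with adjusted p-values. The deposited signal values are read counts divided by a size factor for each library, set separately in each table by the authors. Every deposited value was a whole multiple of a step per library, so 100% of values came out as whole reads within a tolerance of 0.0001 read. The tables hold only genes with at least 61 reads over their 6 libraries. The recovered reads of a library were equal in both of its tables in all 208248 values compared, and 0 differed. In all, 18604 genes were in any table and 17354 in all 4.

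Recovered depth ran from 74206246 to 110452636 reads per library. Counting error was not separated from the spread between libraries. Some genes named had few reads in a group, such as Cyp1a1 in control diet TAC hearts (3.88 normalized reads on average) and Igfbp2 in BCAA-free sham hearts (5.07 to 12.4), so their fold changes rest on few reads. Positions are those of GRCm38 in the annotation used here (GENCODE release 21 numbering for mouse), in which 18547 of the genes were found.

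The design foresaw a count test for raw counts and limma for normalized values. Since the deposited unit was normalized counts, the main test was limma-trend (limma 3.58.1 in R 4.3.3) with robust empirical Bayes on log2(value + 1). Genes with a mean of at least 10 were tested, and calls had a Benjamini-Hochberg adjusted p below 0.05. Each pair of groups was fitted alone, 3 libraries against 3. The difference between diets in the response to TAC was tested in a model of all 12 libraries with 4 group means, each TAC library and its sham libraries taken from the table that holds both. Fold changes are log2 values ± SE on the log2(value + 1) scale, which understates changes of low genes. Normalized reads given per group or per library use size factors set jointly over the 12 libraries instead. Their ratios can therefore differ from the fold changes beside them. Unless another tool is named, adjusted p-values of genes are from limma.

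Before the data were examined, 22 pathway lists and 13 cell type lists were fixed, 35 in all. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 35 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The rule for named genes was also fixed then. It takes, in each pairwise comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 and no overlap between groups. Predicted genes, Rik genes, clones and ribosomal pseudogenes were skipped. It adds the 3 members with the smallest p from each list that was called or had at least 3 called members, a set of 20 genes in every comparison, and the 5 smallest p in each direction for the difference of TAC responses. Genes outside the rule are said to be chosen after their values were seen.

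On simulated reads with 200 genes changed, limma recovered 71.4% of genes changed by a log2 of 1 for TAC on the control diet (17887 genes run), 80.3% for TAC on the BCAA-free diet (17265 genes run), 80.3% for diet in sham hearts (17677 genes run), 70.3% for diet in TAC hearts (17700 genes run) and 53.0% for the difference of TAC responses (17377 genes run). Of changes of 0.5 it recovered 16.9%, 58.7%, 50.8%, 15.4% and 6.06% in the same order. The share of calls on genes left unchanged was 6.61%, 12.6%, 7.45%, 7.03% and 1.11%. A list raised in the simulation was found in all 5 comparisons, and 0 of the 33 lists without raised members were called in any. The simulated genes were drawn independently of each other. In the real libraries the estimated correlation was, for example, 0.656 for matrix genes with TAC on the control diet. The simulation therefore does not show how often camera calls correlated lists that did not change.

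Alternatives fixed in advance were a pseudocount of 0.5 or 5, no filter or a mean of at least 50, TMM or quantile rescaling, limma without the trend, DESeq2 1.42.0 and edgeR 4.0.16 quasi-likelihood on the recovered reads, all 12 libraries in a single fit, a 2-fold threshold, the replicate number as a block, omission of mitochondrially coded genes, and omission of each library in turn. On recovered reads, edgeR called 2768 genes for TAC on the control diet, 1424 for TAC on the BCAA-free diet, 708 for diet in sham hearts, 3072 for diet in TAC hearts and 141 for the difference of TAC responses. DESeq2 called 3629, 1893, 1523, 3816 and 824 in the same order. On the simulated reads its share of calls on genes left unchanged was 19.5%, 17.6%, 18.0%, 17.3% and 16.9%, above that of limma in each comparison. Alternatives chosen after seeing the data were covariates of Rn7sk, Rmrp and Rpph1 or of the atrial genes Sln, Myl7 and Myl4, joint size factors over the 12 libraries, and omission of the 3 libraries highest in Rn7sk, Rmrp and Rpph1. A fit without a library has fewer samples and less power, so a call lost in it need not mean a smaller change. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.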

Results

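RNA from 12 mouse heart samples was compared in a design of diet by surgery, with 3 libraries in each of 4 groups: control diet sham, control diet TAC, BCAA-free sham and BCAA-free TAC. The comparisons ask how pressure overload for 1 week changed cardiac RNA on each diet, how the diet without branched-chain amino acids changed it in sham and in TAC hearts, and whether the response to TAC differed between the diets. Libraries held between 74206246 and 110452636 reads. The first principal component took 45.5% of the variance and set the control diet TAC libraries, at 46.7 to 60.1, apart from all others, at -4.26 or lower. Control diet TAC 3 lay farthest from its group mean, with an SD over genes of 0.283 in log2 units, against 0.138 to 0.213 in the other libraries.

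Some features of the libraries varied within groups, and some also differed between groups. The structured RNAs Rn7sk, Rmrp and Rpph1 together came to 115.5 CPM (reads scaled to the library total) in control diet sham 2, 63.6 in BCAA-free TAC 1, 76.1 in BCAA-free TAC 3 and 19.3 in control diet TAC 3, against 2.06 to 7.79 in the other libraries. Reads of mitochondrially coded genes made up 24.3 ± 2.47% in control diet sham, 18.7 ± 1.09% in control diet TAC, 23.1 ± 0.467% in BCAA-free sham and 22.1 ± 0.326% in BCAA-free TAC hearts (mean ± SD, n = 3). Each control diet TAC library (17.9 to 19.9%) lay below every other library (21.8 to 27.1%). The atrial light chain Myl7 ran from 1405 to 11344 normalized reads between libraries. On the BCAA-free diet it was higher in every TAC library (8343 to 10589) than in every sham library (2860 to 6312). The atrial genes Sln and Myl4 did not overlap there either. Rn7sk, Rmrp and Rpph1 together were at 7.79 to 76.1 CPM in BCAA-free TAC and 3.02 to 3.89 in BCAA-free sham libraries. Atrial RNA and these structured RNAs therefore went with TAC on this diet.

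On the control diet, 38 of 40 matrix, 23 of 30 cell cycle, 11 of 15 hypertrophic marker and 7 of 11 macrophage genes rose with TAC, and 13 of 28 genes of branched-chain amino acid breakdown, 10 of 24 of calcium handling and 8 of 29 of fatty acid oxidation fell. With an estimated correlation no list passed (lowest adjusted p = 0.0649). Nppa, which codes for atrial natriuretic peptide (GRCm38 chromosome 4, 148000722 to 148002079, protein coding), went from 24886 ± 11379 to 170489 ± 43187 normalized reads (mean ± SD, n = 3), a log2 change of 2.84 ± 0.324 (SE, adjusted p = 0.00112). Nppb, its neighbour for brain natriuretic peptide (chromosome 4, 147985788 to 147987205), rose by 1.65. The matrix genes Cthrc1 (chromosome 15, 39076932 to 39087121) and Thbs4 (chromosome 13, 92751590 to 92794818) rose by 5.28 ± 0.26 (adjusted p = 2.57e-05) and 3.62 ± 0.138 (adjusted p = 1.2e-05). In all, 1678 genes rose and 1032 fell of 18305 tested.

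Extracellular matrix genes moved as a block. Of 40 measured members 38 rose, and 40 when adjusted over the list alone, with a median log2 change of 2.04 (camera adjusted p = 3.15e-36, and adjusted p = 0.369 with an estimated correlation). Tnc, a matrix protein of wound repair, rose by 3.84, Lox, which crosslinks collagen, by 3.66, Postn (chromosome 3, 54361109 to 54391037) by 3.52 ± 0.242 and Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), by 2.45 ± 0.271. Of 15 hypertrophic marker genes 11 rose (11 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 6.21e-10, and adjusted p = 0.0649 with an estimated correlation). Uchl1 rose by 1.78. Acta1, the skeletal actin of the fetal heart programme (chromosome 8, 123891769 to 123894751), rose by 2.53 ± 0.351, and Myh7, the slow myosin heavy chain, by 1.39 (adjusted p = 0.034). Without control diet TAC 3, Acta1 did not pass (adjusted p = 0.061). Myh7 did not pass without TAC 1 (adjusted p = 0.0869), sham 1 (0.115), sham 2 (0.0525) or sham 3 (0.0795). The list shares Myl4 with the atrial markers, whose levels varied between libraries. Among the largest rises of other genes were those of Sprr1a (5.49), C1qtnf3 (4.47), Cemip (3.94), Serpinb1c (3.76) and Col9a2 (3.74).

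Of 30 cell cycle genes 23 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 7.34e-16, and adjusted p = 0.422 with an estimated correlation). Mcm5, part of the helicase that opens DNA for replication (chromosome 8, 75109569 to 75128439), rose by 1.10, Mcm6 by 0.90 and Tyms by 1.40. Of 11 macrophage markers 7 rose (10 adjusted over the list alone; camera adjusted p = 8.2e-08, and adjusted p = 0.422 with an estimated correlation), among them the complement genes C1qa (0.84), C1qb (0.94) and C1qc (0.78). Of 25 inflammatory genes 9 rose (16, and 1 lower, adjusted over the list alone; camera adjusted p = 8.8e-07, and adjusted p = 0.186 with an estimated correlation), with Spp1 at 3.01, Ccl8 at 3.14 and Lgals3 at 1.62. Of 24 interferon response genes 6 rose (7 adjusted over the list alone), Isg15 by 0.99 (camera adjusted p = 0.000179, and adjusted p = 0.663 with an estimated correlation). Of 11 fibroblast markers 7 rose, such as Mfap5 (2.32) and Lum (1.33), and 2 fell, such as Scara5 at -0.94 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.458 with an estimated correlation).

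Of 32 genes of the amino acid response through ATF4, 9 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.458 with an estimated correlation). Gdf15, a secreted stress factor, rose by 2.16, Nupr1 by 1.54 and Pycr1, of proline synthesis, by 1.17. Of 17 oxidative stress and metallothionein genes 5 rose (7 adjusted over the list alone; camera adjusted p = 0.00232, and adjusted p = 0.649 with an estimated correlation), with Mt2 at 1.91, Hmox1 at 1.29 and Gpx3 at 1.26.

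Of 28 genes of branched-chain amino acid breakdown 13 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 3.28e-09, and adjusted p = 0.458 with an estimated correlation). Bckdha, a subunit of the branched-chain ketoacid dehydrogenase (chromosome 7, 25629946 to 25658981), fell from 8899 ± 307.1 to 4946 ± 292 normalized reads (mean ± SD, n = 3), a log2 change of -0.86 ± 0.0936 (SE, adjusted p = 0.000886). Ppm1k, the phosphatase that activates that complex (chromosome 6, 57506502 to 57535468), changed by -0.65, Pcca by -0.64 and Ivd by -0.63. Of 29 fatty acid oxidation genes 8 fell (17 adjusted over the list alone; camera adjusted p = 7.76e-09, and adjusted p = 0.458 with an estimated correlation), with Hadha at -0.63. Of 22 genes of the tricarboxylic acid cycle 5 fell (11 adjusted over the list alone; camera adjusted p = 5.25e-06, and adjusted p = 0.649 with an estimated correlation), with Suclg2 at -0.62. Of 55 nuclear genes of oxidative phosphorylation 3 fell (2 adjusted over the list alone; camera adjusted p = 6.21e-06, and adjusted p = 0.821 with an estimated correlation), beside the lower mitochondrial read share of these libraries. Of 17 PPAR alpha responsive genes 4 fell (5 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.458 with an estimated correlation), with Vldlr at -0.76. Of 24 calcium handling and ion channel genes 10 fell (14 adjusted over the list alone; camera adjusted p = 1e-07, and adjusted p = 0.0649 with an estimated correlation). Among these were Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.82; chromosome 5, 122453513 to 122502225), Hrc (-0.79) and the potassium channel subunit Kcnv2 (-2.02). Cngb3 (-2.08), Acsm5 (-1.90) and Inmt (-1.90) were among the largest falls of other genes.

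Lists with fewer called members followed. Of 10 adipocyte markers 3 rose (5 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 0.00101, and adjusted p = 0.565 with an estimated correlation). Of 67 cytosolic ribosomal protein genes 1 passed, Rpl3 at 0.65 (1 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.916 with an estimated correlation). That list was not called without control diet TAC 3 (camera adjusted p = 0.969) or sham 3 (0.574). Of 7 epicardial markers 1 passed, Krt8 at 2.32 (1 adjusted over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.661 with an estimated correlation), and the list was not called without TAC 1 (camera adjusted p = 0.0565), TAC 3 (0.112) or sham 3 (0.205). Camera did not call glucocorticoid-responsive genes (median 0.11, adjusted p = 0.0798), circadian clock genes (-0.09, adjusted p = 0.219) or red blood cell genes (-0.35, adjusted p = 0.159). The first passed without sham 2 (adjusted p = 0.00161), the next without sham 1 (0.0363) and the last without TAC 3 (0.00431) or sham 3 (0.0353). Also not called were ribosome biogenesis (median 0.10, adjusted p = 0.338), cardiomyocyte (-0.25, adjusted p = 0.406), nerve (-0.12) and skeletal muscle markers (0.07, both adjusted p = 0.456), endothelial markers (-0.12) and the unfolded protein response (0.08, both adjusted p = 0.613), aminoacyl-tRNA synthetases (-0.02, adjusted p = 0.733) and glycolysis (0.10, adjusted p = 0.919). In 6 more uncalled lists the median and mean had opposite signs. These were lymphocyte (median -0.16, mean 0.14, adjusted p = 0.958), neutrophil (-0.15, 0.12, adjusted p = 0.674) and atrial markers (0.44, -0.21, adjusted p = 0.958), for which camera gave an upward direction, and smooth muscle markers (-0.10, 0.10, adjusted p = 0.919), ubiquitin and autophagy genes (0.04, -0.04, adjusted p = 0.719) and sterol synthesis (-0.01, 0.01, adjusted p = 0.613), for which it gave a downward one.

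The limma test called 2710 genes, 959 of them changed at least 2-fold, and the authors' deposited table held 3629 genes with an adjusted p under 0.05. The 3 libraries of each group did not overlap in 34.8% of tested genes, against 10% by chance. The count was 1365 without TAC 1, 4678 without TAC 3, 1456 without sham 1, 1384 without sham 2, which was also the library high in Rn7sk, and 1354 without sham 3. Of 82 called genes among those named by the fixed rule, 60 kept their call whichever library was left out.

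Leaving out a library also moved the number of called members of some lists, here given at the extremes for TAC on the control diet. Without TAC 3 it went from 14 to 24 for branched-chain amino acid breakdown, from 8 to 25 for fatty acid oxidation, from 3 to 43 for oxidative phosphorylation and from 5 to 21 for the tricarboxylic acid cycle. Fatty acid oxidation had 1 without sham 3, the tricarboxylic acid cycle 1 without sham 2 or sham 3, and oxidative phosphorylation none without sham 2. The amino acid response went from 11 to 5 without sham 1, the interferon response from 6 to 1 without sham 2, fibroblast markers from 9 to 3 without TAC 1 or sham 3, and oxidative stress genes from 5 to 3 without sham 1. PPAR alpha responsive genes went from 4 to 1 without sham 1 or sham 3, epicardial markers from 1 to 2 without sham 1, and adipocyte markers from 3 to 7 without TAC 2 and to none without TAC 1, sham 2 or sham 3.

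On the BCAA-free diet 25 of 40 matrix and 7 of 15 hypertrophic marker genes rose with TAC. With an estimated correlation no list passed (lowest adjusted p = 0.327). Igfbp2, which binds insulin-like growth factors (chromosome 1, 72824503 to 72852474), rose by 4.60 ± 0.326 (SE, adjusted p = 5.19e-05) from only 5.07 to 12.4 normalized reads in sham libraries, and Eln, elastin (chromosome 5, 134702593 to 134747323), rose by 1.00 ± 0.0701 (adjusted p = 5.19e-05). Nppa went from 19925 ± 4465 to 73895 ± 19297 normalized reads (mean ± SD, n = 3), a log2 change of 1.88 ± 0.268 (adjusted p = 0.0285). That call was lost without TAC 1 (adjusted p = 0.059), TAC 3 (0.0878), sham 2 (0.11) or sham 3 (0.0674). In all, 583 genes rose and 777 fell of 17611 tested.

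Of 40 matrix genes 25 rose on this diet (35 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 2.44e-34, and adjusted p = 0.327 with an estimated correlation). Cthrc1 rose by 2.29, Timp1, an inhibitor of matrix proteases, by 2.19, Mfap4 by 1.37 and Lum by 0.69. Postn rose by 1.66 (adjusted p = 0.0489), a call lost without TAC 1 (adjusted p = 0.0977), TAC 3 (0.129), sham 1 (0.149), sham 2 (0.0955) or sham 3 (0.139). Col1a1, at 1.14, did not pass (adjusted p = 0.102), except without TAC 2 (adjusted p = 1.82e-06). Of 15 hypertrophic marker genes 7 rose (10 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.09e-11, and adjusted p = 0.327 with an estimated correlation). Ankrd1, a stretch-responsive muscle protein, rose by 1.27, Uchl1 by 0.52 and Fhl1 by 0.48. Acta1 rose by 3.02 (adjusted p = 0.0171), a call lost without TAC 3 (adjusted p = 0.0575), sham 1 (0.0639), sham 2 (0.0739) or sham 3 (0.0645). Beside these lists, the atrial markers had a median of 0.94 with 6 measured (camera adjusted p = 0.000121, and adjusted p = 0.327 with an estimated correlation). Limma called 0 of the 6, with 4 higher at an unadjusted p under 0.05, 0 by edgeR and 3 by DESeq2, and 4 were higher adjusted over the list alone. Sln, at 1.34, Myl7, at 1.19, and Myl4, at 1.16, passed without sham 2 (adjusted p = 0.0457, 0.0153 and 0.00616).

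Of 30 cell cycle genes limma called 0 on this diet, edgeR 0 and DESeq2 2, both lower, while 3 were higher and 3 lower at an unadjusted p under 0.05. The list had a median of 0.16 (camera adjusted p = 0.412), and it was called higher without sham 2 (camera adjusted p = 0.0311). Of 11 macrophage markers 4 rose (6 adjusted over the list alone; camera adjusted p = 3.55e-05), and of 22 inflammatory genes 3 rose (4 adjusted over the list alone; camera adjusted p = 6.13e-05), with Ccl8 at 2.96, Spp1 at 2.11 and Cxcl16 at 0.59. For both lists the adjusted p = 0.327 with an estimated correlation. Of 11 fibroblast markers 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000532, and adjusted p = 0.327 with an estimated correlation), with Pi16 at 0.96 and Mfap5 at 1.11. Of 11 cardiomyocyte markers 6 rose (6 adjusted over the list alone; camera adjusted p = 7.59e-05, and adjusted p = 0.327 with an estimated correlation), among them the sarcomere genes Tnnc1 (0.60), Actc1 (0.54) and Mybpc3 (0.40). Of 9 adipocyte markers 2 rose (4 adjusted over the list alone; camera adjusted p = 7.07e-05, and adjusted p = 0.327 with an estimated correlation).

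Of 21 genes of the unfolded protein response 8 fell (11, and 1 higher, adjusted over the list alone), with a median of -0.21 (camera adjusted p = 2.64e-07, and adjusted p = 0.327 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, changed by -0.37 and Canx by -0.36. Of 24 calcium handling genes 8 fell (12, and 2 higher, adjusted over the list alone; camera adjusted p = 3.55e-05, and adjusted p = 0.327 with an estimated correlation), with Atp2a2 at -0.41. Of 28 genes of branched-chain amino acid breakdown 6 fell (10, and 1 higher, adjusted over the list alone; camera adjusted p = 6.13e-05, and adjusted p = 0.416 with an estimated correlation), with Ppm1k at -0.38, Klf15 at -0.41 and Bckdha at -0.33 ± 0.0589 (SE, adjusted p = 0.00591). Of 17 PPAR alpha responsive genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.000145, and adjusted p = 0.327 with an estimated correlation), with Vldlr at -0.43. Of 18 clock genes 3 fell, Arntl (-1.01), Clock (-0.54) and Nr1d1 (-0.62), and 2 rose (3 and 2 adjusted over the list alone), with a median of 0.15, and camera did not call the list (adjusted p = 0.584). Ano10 (-1.13) and Abca12 (-1.01) were among the largest falls.

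Other lists were called with few changed members on the BCAA-free diet. Of 67 ribosomal protein genes 4 rose (1 adjusted over the list alone; camera adjusted p = 2.29e-08, and adjusted p = 0.6 with an estimated correlation). Of 55 oxidative phosphorylation genes 2 rose, with a median of 0.08 (camera adjusted p = 0.000251, and adjusted p = 0.681 with an estimated correlation). Of 4 neutrophil genes 1 rose (4 adjusted over the list alone; camera adjusted p = 0.00522), and the epicardial list had a median of 1.01 (1 higher adjusted over the list alone; camera adjusted p = 0.0018). For both the adjusted p = 0.327 with an estimated correlation. Fatty acid oxidation, with 3 of 29 lower (5 adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.602 with an estimated correlation), was not called without TAC 1 (camera adjusted p = 0.203). The interferon response, with 1 of 24 higher (camera adjusted p = 0.0041, and adjusted p = 0.613 with an estimated correlation), was not called without TAC 1 (camera adjusted p = 0.0543) or sham 2 (0.27). The amino acid response had 3 of 32 higher, among them Nupr1 at 1.02, and 2 lower, among them Aldh1l2 at -0.59 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0348, and adjusted p = 0.327 with an estimated correlation). It was not called without TAC 3 (camera adjusted p = 0.0862) or sham 3 (0.0889). Ubiquitin and autophagy, with 3 of 23 lower (3 adjusted over the list alone; camera adjusted p = 0.0392, and adjusted p = 0.327 with an estimated correlation), among them the ligase gene Fbxo32 at -0.51, was not called without TAC 2 (camera adjusted p = 0.0853), TAC 3 (0.0672) or sham 2 (0.0725).

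The limma test called 1360 genes on the BCAA-free diet, 112 of them changed at least 2-fold, and the authors' deposited table held 1891 genes with an adjusted p under 0.05. Groups did not overlap in 28.1% of tested genes, against 10% expected by chance. The count was 878 without TAC 3, 681 without sham 1, 647 without sham 2 and 546 without sham 3, and 297 without both libraries high in Rn7sk, TAC 1 and TAC 3. With the atrial genes, which went with TAC here, as a covariate it was 5. Of 72 called genes among those named by the fixed rule 41 kept their call whichever library was left out.

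The number of called members of a list moved too for TAC on the BCAA-free diet. For matrix genes it went from 25 to 12 without sham 3, for hypertrophic marker genes from 7 to 4 without TAC 3 or sham 3, and for the unfolded protein response from 8 to 2 without sham 1 or sham 3. Macrophage markers went from 4 to 8 without TAC 2 and to none without TAC 3, sham 1 or sham 3, inflammatory genes from 3 to 5 without TAC 2, and fibroblast markers from 6 to 3 without sham 1. Calcium handling went from 8 to 1 without sham 3, PPAR alpha responsive genes from 3 to 1 without TAC 1, TAC 3, sham 2 or sham 3, and clock genes from 5 to 3 without TAC 3, sham 2 or sham 3. Oxidative phosphorylation went from 2 to 4 without TAC 3 and to none without TAC 1, TAC 2, sham 1 or sham 2, and ribosomal proteins from 4 to 8 without TAC 3 and to none without sham 1 or sham 2. None were left for fatty acid oxidation without TAC 3, sham 2 or sham 3, adipocyte markers without sham 1 or sham 3, the interferon response without TAC 1, TAC 3, sham 2 or sham 3, and neutrophil markers without TAC 2, TAC 3 or sham 2.

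In sham hearts 17 of 40 matrix, 9 of 30 cell cycle and 4 of 24 interferon response genes were lower on the BCAA-free diet, 1 cell cycle gene was higher, and 6 of 28 genes of branched-chain amino acid breakdown were higher. None of these lists passed with an estimated correlation (adjusted p = 0.199, 0.486, 0.486 and 0.199). Col1a1 went from 6168 ± 649.7 to 2873 ± 198.5 normalized reads (mean ± SD, n = 3), a log2 change of -1.10 ± 0.0829 (SE, adjusted p = 0.000673). Acta1 fell by 1.55 on the log2 scale (adjusted p = 0.00322). Ppm1k rose by 0.60 ± 0.0702 (adjusted p = 0.00391). In all, 227 genes were higher on the BCAA-free diet and 406 lower, of 17862 tested.

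Of 40 matrix genes 17 were lower on the BCAA-free diet in sham hearts (33 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.18e-25, and adjusted p = 0.199 with an estimated correlation). Col1a2, at -0.89, and Col5a1, at -0.72, were among them. Of 30 cell cycle genes 9 were lower and 1, Cenpf, higher (24 and 2 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.4e-11, and adjusted p = 0.486 with an estimated correlation). Ccnb2, a cyclin of mitosis, changed by -1.59, a call lost without BCAA-free sham 1 (adjusted p = 0.0643) or control diet sham 3 (0.0859). Cenpf, at 0.57, lost its call without BCAA-free sham 1 (adjusted p = 0.0961), BCAA-free sham 2 (0.0689) or control diet sham 3 (0.0698). Of 24 interferon response genes 4 were lower (12 adjusted over the list alone; camera adjusted p = 1.89e-11, and adjusted p = 0.486 with an estimated correlation), and of 22 inflammatory genes 4 (5 adjusted over the list alone; camera adjusted p = 0.00044, and adjusted p = 0.199 with an estimated correlation). Of the latter, Tgfb1 changed by -0.52 and Cxcl16 by -0.71, and both lost their calls without BCAA-free sham 1 (adjusted p = 0.0643 and 0.0672). Of 10 endothelial markers 1 was lower (7 adjusted over the list alone; camera adjusted p = 9.92e-05, and adjusted p = 0.333 with an estimated correlation). Of 23 sterol and fatty acid synthesis genes 2 were lower (3, and 1 higher, adjusted over the list alone; camera adjusted p = 0.00553, and adjusted p = 0.641 with an estimated correlation). The desaturase gene Scd2, at -0.59, lost its call without BCAA-free sham 1 (adjusted p = 0.0555). Prnd (-2.17) and Sez6l2 (-1.79) fell too and passed whichever library was left out.

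Of 28 genes of branched-chain amino acid breakdown 6 were higher in sham hearts without dietary BCAA (20, and 1 lower, adjusted over the list alone), with a median of 0.18 (camera adjusted p = 2.2e-12, and adjusted p = 0.199 with an estimated correlation). Aldh6a1, of the valine pathway, rose by 0.38, a call lost without BCAA-free sham 1 (adjusted p = 0.076). Bckdha, at 0.24, did not pass (adjusted p = 0.0541), except without control diet sham 2 (adjusted p = 0.0443). Of 24 calcium handling genes 2 were higher (5 adjusted over the list alone; camera adjusted p = 0.000555, and adjusted p = 0.199 with an estimated correlation), with Kcnv2 at 0.59. Of 55 oxidative phosphorylation genes limma called 0, with 14 higher at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2, and the median was 0.12 (camera adjusted p = 2.07e-08, and adjusted p = 0.641 with an estimated correlation). Of 29 fatty acid oxidation genes limma called 0, with 10 higher at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2, and the median was 0.09 (camera adjusted p = 2.45e-05, and adjusted p = 0.199 with an estimated correlation). Of 22 tricarboxylic acid cycle genes 1 was higher, Idh2 at 0.38 (1 adjusted over the list alone; camera adjusted p = 0.00025, and adjusted p = 0.641 with an estimated correlation), a call lost without BCAA-free sham 1 (adjusted p = 0.0828) or sham 3 (0.0608). Of 16 glucocorticoid-responsive genes 1 was higher (2 adjusted over the list alone; camera adjusted p = 0.00044, and adjusted p = 0.596 with an estimated correlation), and of 23 ubiquitin and autophagy genes 1 (4 adjusted over the list alone; camera adjusted p = 0.00226, and adjusted p = 0.199 with an estimated correlation). Outside the lists Pim3, a kinase gene, rose by 0.83, a call lost without BCAA-free sham 1 (adjusted p = 0.0555). Cyp1a1, a xenobiotic-metabolizing cytochrome P450 (chromosome 9, 57687928 to 57703824), rose by 2.30 ± 0.387 (adjusted p = 0.0182), a call lost without BCAA-free sham 1 (adjusted p = 0.0601), sham 2 (0.059) or sham 3 (0.0741) or control diet sham 3 (0.0719).

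The calls of 7 more lists in sham hearts were lost when a single library was left out. Neutrophil genes (3 measured, median -0.83, 1 lower adjusted over the list alone; camera adjusted p = 0.0482, and adjusted p = 0.51 with an estimated correlation) were not called without BCAA-free sham 2 (camera adjusted p = 0.146), control diet sham 1 (0.0765) or control diet sham 2 (0.219). PPAR alpha responsive genes (median 0.08, camera adjusted p = 0.0246, and adjusted p = 0.641 with an estimated correlation) were not called without BCAA-free sham 2 (camera adjusted p = 0.441), control diet sham 1 (0.0765) or control diet sham 2 (0.111). The amino acid response (-0.16, camera adjusted p = 0.0358, and adjusted p = 0.641 with an estimated correlation) was not called without BCAA-free sham 3 (camera adjusted p = 0.0584) or control diet sham 2 (0.479). Macrophage markers (-0.24, camera adjusted p = 0.0246, and adjusted p = 0.641 with an estimated correlation) were not called without BCAA-free sham 1 (camera adjusted p = 0.0548), BCAA-free sham 3 (0.0523), control diet sham 1 (0.0919) or control diet sham 3 (0.0789). Fibroblast markers (-0.18, camera adjusted p = 0.0495, and adjusted p = 0.641 with an estimated correlation) were not called without BCAA-free sham 1 (camera adjusted p = 0.0651), sham 2 (0.0956) or sham 3 (0.0523) or control diet sham 1 (0.126). Hypertrophic marker genes (-0.10, camera adjusted p = 0.0495, and adjusted p = 0.486 with an estimated correlation) were not called without BCAA-free sham 2 (camera adjusted p = 0.0668), BCAA-free sham 3 (0.106) or control diet sham 2 (0.222). Ribosomal protein genes (0.08, camera adjusted p = 2.45e-05, and adjusted p = 0.646 with an estimated correlation) were not called without control diet sham 3 (camera adjusted p = 0.343).

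The limma test called 633 genes for diet in sham hearts, 57 of them changed at least 2-fold, and the authors' deposited table held 1529 genes with an adjusted p under 0.05. Groups did not overlap in 26.1% of tested genes, against 10% expected by chance. The count was 50 without BCAA-free sham 1, 225 without BCAA-free sham 2, 136 without BCAA-free sham 3, 184 without control diet sham 3 and 1071 without control diet sham 2, the library high in Rn7sk. Of 49 called genes among those named by the fixed rule, 8 kept their call whichever library was left out: Acta1, Col1a1, Col1a2, Col5a1, Kcnv2, Ppm1k, Prnd and Sez6l2.

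The number of called members in each of the lists for diet in sham hearts moved with a library left out, which also lowers power. Without BCAA-free sham 1 matrix genes went from 17 to 3 and branched-chain amino acid breakdown from 6 to 1, and none were left for inflammatory genes, sterol and fatty acid synthesis, cell cycle genes and the interferon response. The interferon response also had none without BCAA-free sham 2, BCAA-free sham 3 or control diet sham 3, and cell cycle genes none without control diet sham 3. Without control diet sham 2 cell cycle genes went from 10 to 17, the interferon response from 4 to 14, endothelial markers from 1 to 4 and glucocorticoid-responsive genes from 1 to 6. The single call among endothelial markers was lost without BCAA-free sham 1, BCAA-free sham 3, control diet sham 1 or control diet sham 3. Those among glucocorticoid-responsive and among ubiquitin and autophagy genes were lost without any of the BCAA-free sham libraries. Ubiquitin and autophagy had 2 without control diet sham 1, and calcium handling went from 2 to 1 without BCAA-free sham 2 or sham 3. The single call in the tricarboxylic acid cycle was lost without BCAA-free sham 1 or sham 3.

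In TAC hearts 38 of 40 matrix, 28 of 30 cell cycle, 18 of 24 interferon response, 9 of 11 macrophage and 6 of 15 hypertrophic marker genes were lower on the BCAA-free diet. Higher were 17 of 28 genes of branched-chain amino acid breakdown, 15 of 29 of fatty acid oxidation, 21 of 55 of oxidative phosphorylation and 9 of 22 of the tricarboxylic acid cycle. With an estimated correlation no list passed (lowest adjusted p = 0.303). Postn was at 9979 ± 3034 normalized reads on the BCAA-free and 67756 ± 24661 on the control diet (mean ± SD, n = 3), a log2 difference of -2.74 ± 0.29 (SE, adjusted p = 0.000686). Cdk1, the kinase that drives mitosis (chromosome 10, 69335146 to 69352938), differed by -2.92 ± 0.212 (adjusted p = 0.00025). Bckdha differed by 0.77 ± 0.0935 (adjusted p = 0.000927) and Ppm1k by 0.88 (adjusted p = 0.00176). In all, 1124 genes were higher and 1901 lower on the BCAA-free diet, of 18039 tested. The plot of 8 genes by group shows Postn and Bckdha, but not Cdk1 or Ppm1k, in each library.

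**Figure D1:**
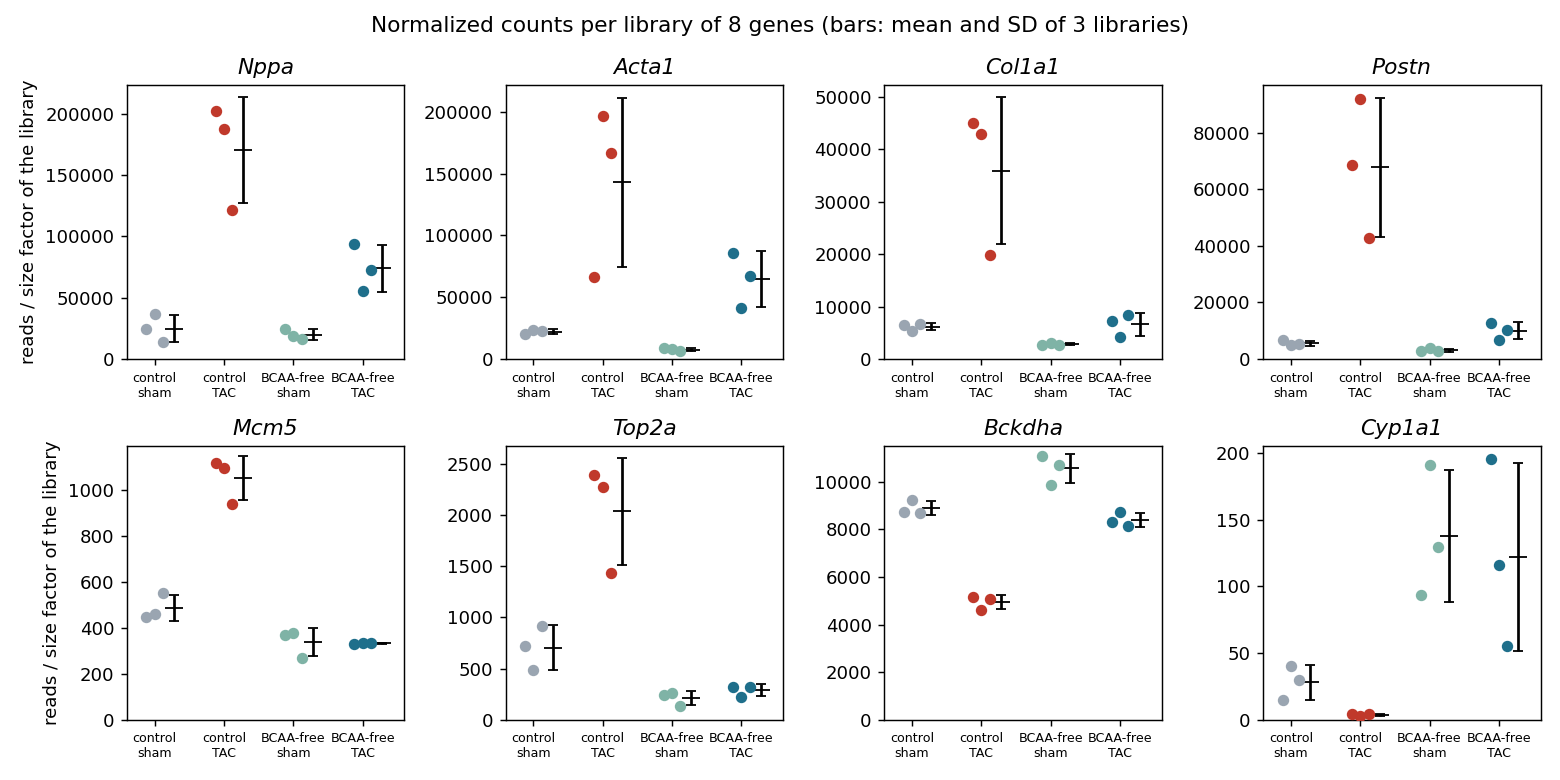
Normalized reads of 8 genes in the 4 groups, with reads divided by a size factor set jointly over the 12 libraries; dots are libraries and bars give the mean ± SD (n = 3). Col1a1 and Postn were highest in control diet TAC hearts, at 35915 ± 13949 and 67756 ± 24661, and Bckdha was lowest there, at 4946 ± 292.

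Of 40 matrix genes 38 were lower on the BCAA-free diet in TAC hearts (39 adjusted over the list alone), with a median of -1.74 (camera adjusted p = 1.17e-29, and adjusted p = 0.389 with an estimated correlation). Cthrc1 differed by -3.73, Col1a1 by -2.41, Loxl2 by -1.74 and Lum by -1.02. Of 30 cell cycle genes 28 were lower (29 adjusted over the list alone), with a median of -1.87 (camera adjusted p = 4.84e-26, and adjusted p = 0.303 with an estimated correlation), with Ube2c at -2.66 and Mcm5 at -1.65. Of 24 interferon response genes 18 were lower (19 adjusted over the list alone; camera adjusted p = 2.46e-12, and adjusted p = 0.389 with an estimated correlation), with Isg15 at -1.69, Ifi44 at -1.61 and Bst2 at -1.20. Of 25 inflammatory genes 9 were lower (11 adjusted over the list alone; camera adjusted p = 1.84e-06, and adjusted p = 0.389 with an estimated correlation), with the chemokine Cxcl10 at -2.20 and Lgals3 at -1.56. Of 11 macrophage markers 9 were lower (9, and 1 higher, adjusted over the list alone; camera adjusted p = 4.13e-05, and adjusted p = 0.394 with an estimated correlation), with Fcgr1 at -1.28, Cd68 at -0.93 and C1qb at -0.86. Of 11 fibroblast markers 6 were lower and 2 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.00584, and adjusted p = 0.394 with an estimated correlation), with Mfap5 at -1.54 and Scara5 at 0.92. Sprr1a (-4.21), C1qtnf3 (-4.37) and P4ha3 (-4.05), a collagen prolyl hydroxylase gene, had some of the largest negative differences.

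Of 15 hypertrophic marker genes 6 were lower on the BCAA-free diet in TAC hearts (7 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 2.53e-05, and adjusted p = 0.389 with an estimated correlation). Nppa differed by -1.20 ± 0.228 (SE, adjusted p = 0.00742), Uchl1 by -1.32, Fhl1 by -0.92 and Rcan1, a target of calcineurin signalling, by -0.83. Nppb, at -0.30 (adjusted p = 0.452), and Myh7, at -0.38 (adjusted p = 0.569), did not pass, nor did Acta1, at -1.06 (adjusted p = 0.111), except without control diet TAC 1 (adjusted p = 0.0145). Of 32 genes of the amino acid response 11 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00173, and adjusted p = 0.303 with an estimated correlation). Asns, asparagine synthetase, differed by -0.85, Mthfd2, of mitochondrial folate metabolism, by -2.08, Gdf15 by -2.16 and Pycr1 by -1.31. Of 17 oxidative stress genes 8 were lower (9, and 1 higher, adjusted over the list alone; camera adjusted p = 0.00298, and adjusted p = 0.394 with an estimated correlation), with Hmox1 at -0.99 and Gclm at -0.62. Of 21 genes of the unfolded protein response 6 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.394 with an estimated correlation), with Edem1 at -0.66 and Pdia4 at -0.59. This last call was lost without BCAA-free TAC 1 (camera adjusted p = 0.0691), BCAA-free TAC 2 (0.0597) or control diet TAC 3 (0.144). With the replicate number as a block it was lost too (camera adjusted p = 0.0753).

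Of 28 genes of branched-chain amino acid breakdown 17 were higher on the BCAA-free diet in TAC hearts and 1, Bcat1, lower, at -1.40 (24 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 7.2e-12, and adjusted p = 0.394 with an estimated correlation). Klf15, a transcription factor that controls this pathway, was higher by 0.86. Of 55 oxidative phosphorylation genes 21 were higher (35 adjusted over the list alone; camera adjusted p = 4.35e-14, and adjusted p = 0.464 with an estimated correlation), with Cox7a1 at 0.84, beside mitochondrial read shares of 22.1% and 18.7% on the BCAA-free and control diets. Of 29 fatty acid oxidation genes 15 were higher (22 adjusted over the list alone; camera adjusted p = 2.03e-09, and adjusted p = 0.394 with an estimated correlation), with Cpt1b, the entry step for fatty acids into mitochondria, at 0.73. Of 22 tricarboxylic acid cycle genes 9 were higher (14 adjusted over the list alone; camera adjusted p = 3.37e-08, and adjusted p = 0.394 with an estimated correlation), with Idh2 at 0.80 and Suclg2 at 0.61. Of 24 calcium handling genes 9 were higher (11 adjusted over the list alone; camera adjusted p = 1.45e-06, and adjusted p = 0.389 with an estimated correlation), with Kcnv2 at 1.71, Kcnj2 at 1.14 and Hrc at 0.72. Atp2a2, at 0.69, lost its call without BCAA-free TAC 2 (adjusted p = 0.0673) or TAC 3 (0.0543). Of 11 cardiomyocyte markers 6 were higher (8 adjusted over the list alone; camera adjusted p = 0.00354, and adjusted p = 0.394 with an estimated correlation). Of 18 clock genes 7 were higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.394 with an estimated correlation), with Hlf at 1.01, Tef at 0.73 and Per3 at 0.66. Cyp1a1 (4.49 ± 0.452, at 3.88 normalized reads on average in control diet TAC hearts), Inmt (2.79), Hrk (2.27) and Lvrn (2.20) had some of the largest positive differences. Of 67 ribosomal protein genes 1 was higher (median 0.09, camera adjusted p = 0.0335, and adjusted p = 0.842 with an estimated correlation), and the list was not called without BCAA-free TAC 1 (camera adjusted p = 0.214), BCAA-free TAC 2 (0.0995), control diet TAC 1 (0.117) or control diet TAC 2 (0.928).

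The limma test called 3025 genes for diet in TAC hearts, 953 of them changed at least 2-fold, and the authors' deposited table held 3779 genes with an adjusted p under 0.05. Groups did not overlap in 36.2% of tested genes, against 10% expected by chance. The count was 1936 without BCAA-free TAC 1, 1195 without BCAA-free TAC 2, 1525 without BCAA-free TAC 3, 1600 without control diet TAC 1 and 6025 without control diet TAC 3, and 535 without both BCAA-free TAC libraries high in Rn7sk, TAC 1 and 3. Of 92 called genes among those named by the fixed rule, 67 kept their call whichever library was left out. This comparison shares its control diet TAC libraries with that of TAC on the control diet, so the opposite directions in both are not independent.

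The number of called members of a list moved for diet in TAC hearts as well. Without control diet TAC 3 oxidative phosphorylation went from 21 to 55, fatty acid oxidation from 15 to 28, the tricarboxylic acid cycle from 9 to 22, cardiomyocyte markers from 6 to 10 and ribosomal proteins from 1 to 25. Without BCAA-free TAC 2 oxidative phosphorylation had 1, fatty acid oxidation 1 and the tricarboxylic acid cycle 2, and the last pair had 1 and 2 without BCAA-free TAC 3 as well. In the same fit without BCAA-free TAC 2, branched-chain amino acid breakdown went from 18 to 11, calcium handling from 9 to 3, fibroblast markers from 8 to 3 and oxidative stress genes from 8 to 3. Cardiomyocyte markers had none without BCAA-free TAC 1, 2 or 3, and clock genes went from 8 to 3 without BCAA-free TAC 3. The unfolded protein response went from 7 to 4 without BCAA-free TAC 2, BCAA-free TAC 3 or control diet TAC 1. The single call among ribosomal proteins was lost in every fit but that without control diet TAC 3.

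**Figure D2:**
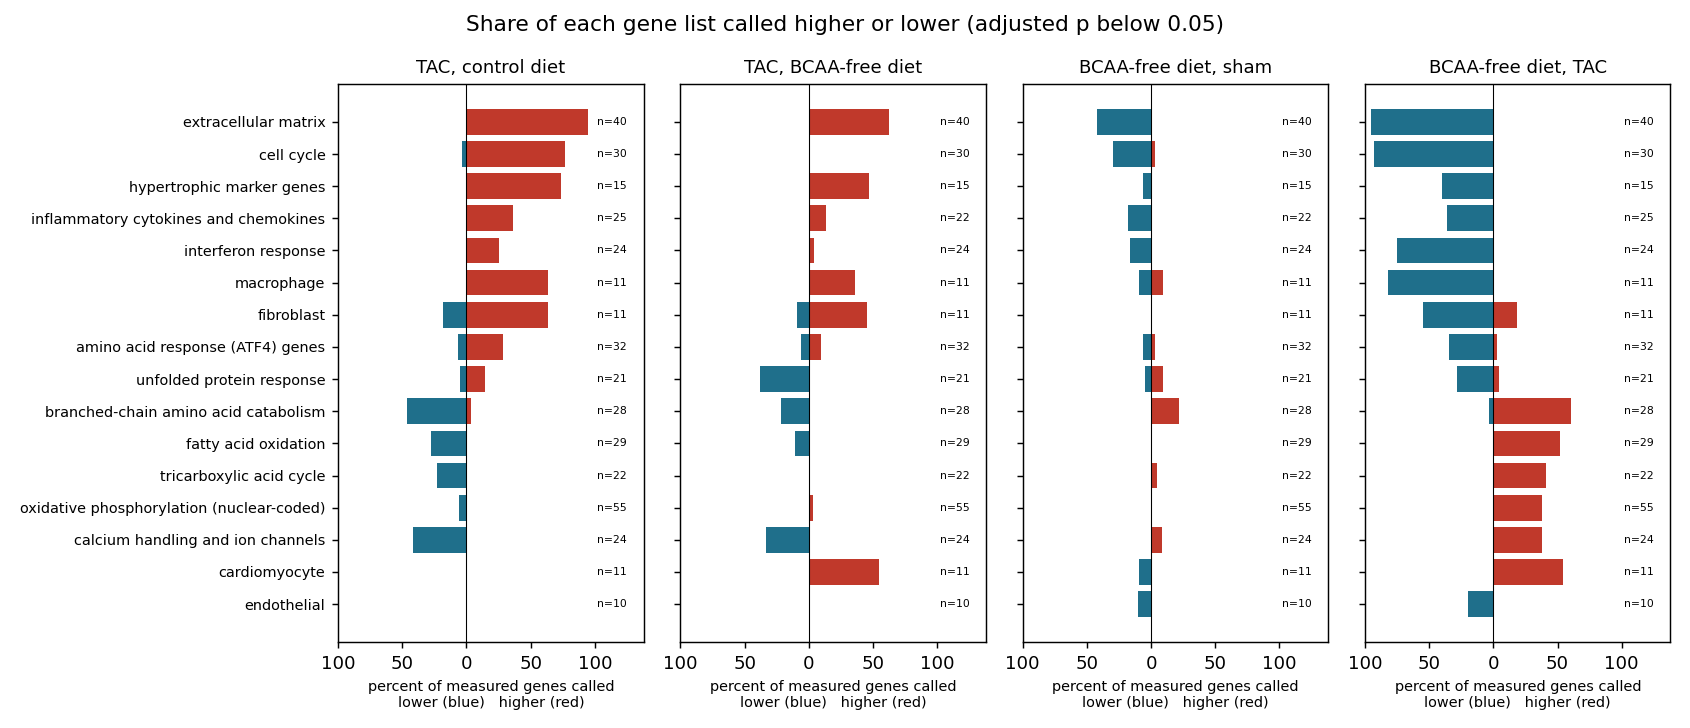
Percent of the measured genes of 16 lists called higher (red) or lower (blue) in the 4 comparisons of pairs of groups, with the number measured printed beside each bar; the scale runs in percent of the list. Among 40 matrix genes, 38 rose with TAC on the control diet and 25 on the BCAA-free diet.

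Responses to TAC on both diets were compared across genes. The 2 TAC comparisons have no library in common. Across 17481 genes their log2 changes had a Pearson r of 0.534 and a Spearman rho of 0.520, where genes are not independent replicates. Of genes in both, 337 were called higher on both diets, against 53.2 for independent lists, and 354 lower, against 45.8. Only 2 were called lower on the control and higher on the BCAA-free diet, against 34.4 for independent lists, and 0 the other way, against 70.8. Of 2626 genes called on the control diet 2421, or 92.2%, had the same sign on the BCAA-free diet.

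**Figure D3:**
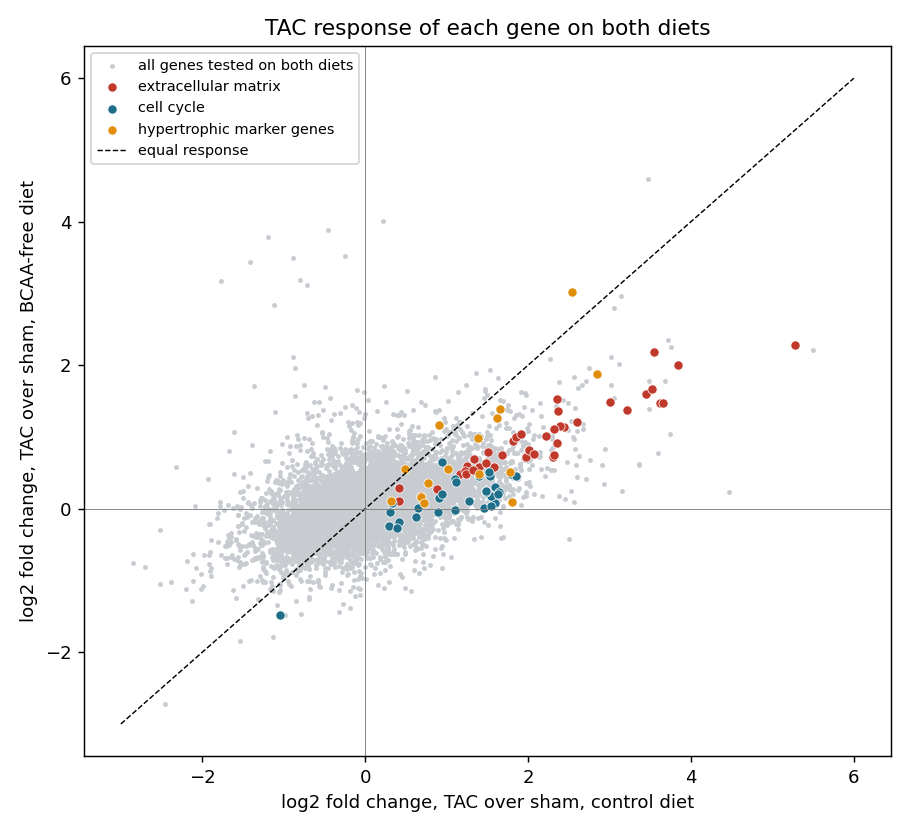
Log2 fold change with TAC on the control diet (horizontal) and on the BCAA-free diet (vertical) for the genes of the extracellular matrix, cell cycle and hypertrophic marker lists; the dashed line marks an equal response. The slopes through 0 were 0.460 for matrix, 0.203 for cell cycle and 0.672 for hypertrophic marker genes.

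The difference itself was tested in a model of all 12 libraries. Serpinb1a, a protease inhibitor gene (chromosome 13, 32842092 to 32851185), had a response to TAC lower by a log2 of -2.58 ± 0.284 on the BCAA-free diet (SE, adjusted p = 0.00587). Negative differences also passed for Star, of steroid synthesis (-1.46), Clu, clusterin (-1.32; chromosome 14, 65968483 to 65981547), Uchl1 (-1.27; chromosome 5, 66676091 to 66687234) and Tspo (-0.98; chromosome 15, 83563592 to 83574203). Positive ones passed for mt-Tf, a mitochondrial tRNA (1.74), and Cxcl14 (1.29). Of 17493 genes tested 88 had a negative and 30 a positive difference. Of the 88, 30 were called higher with TAC on both diets and 58 on the control diet alone.

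Of 40 matrix genes 7 had a smaller response on the BCAA-free diet by this test (30 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 3.26e-30, and adjusted p = 0.275 with an estimated correlation). Among them, and named by the fixed rule for TAC on the control diet rather than for this test, Lox differed by -2.18 and Thbs4 by -2.14, while Cthrc1, at -2.99, lost its call without BCAA-free sham 2 (adjusted p = 0.0597). Postn, at -1.86, did not pass (adjusted p = 0.0647), except without control diet TAC 3 (adjusted p = 0.0145) or BCAA-free TAC 1 (0.0382), nor did Col1a1, at -1.31 (adjusted p = 0.191), except without control diet TAC 3 (0.0193). Of 30 cell cycle genes 4 passed, all negative (24 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 2.06e-20, and adjusted p = 0.22 with an estimated correlation). Mcm5, at -1.12, kept its call without control diet TAC 3, control diet sham 3, BCAA-free TAC 1 or BCAA-free sham 3, and lost it in the other 8 fits with a library left out (adjusted p from 0.0512 to 0.0882). Of 15 hypertrophic marker genes 2 passed, Uchl1 and Fhl1 (3 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00012, and adjusted p = 0.22 with an estimated correlation). Fhl1 kept its call without control diet TAC 1 or TAC 3, and lost it in the other 10 fits (adjusted p from 0.0585 to 0.154). Nppa, at -0.97 ± 0.48 (adjusted p = 0.389), Nppb, at -0.26 (adjusted p = 0.773), and Acta1, at 0.49 (adjusted p = 0.744), did not pass, so a different response was not shown for them. Bckdha had a difference of 0.53 ± 0.105 (adjusted p = 0.0401), a call that held in only 1 of the 12 fits with a library left out, that without control diet TAC 3. In the other fits its adjusted p ran from 0.053 (without control diet TAC 1) to 0.138 (without BCAA-free sham 2). In the fits that lost the call the difference of Bckdha stayed between 0.47 and 0.56. Of 28 genes of branched-chain amino acid breakdown Bckdha was the 1 that passed (10, and 1 lower, adjusted over the list alone), with a median of 0.30 (camera adjusted p = 2.64e-09, and adjusted p = 0.32 with an estimated correlation).

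The limma test called 118 genes for the difference of TAC responses, 56 of them with a difference of at least 2-fold. The count was 47 without control diet TAC 2, 1755 without control diet TAC 3, 60 without control diet sham 1, 23 without control diet sham 2 and 29 without control diet sham 3. On the BCAA-free diet it was 17 without TAC 2, 17 without TAC 3, 24 without sham 1, 16 without sham 2 and 69 without sham 3, and it was 8 without the 3 libraries highest in Rn7sk, Rmrp and Rpph1 (control diet sham 2, BCAA-free TAC 1 and BCAA-free TAC 3). Of 11 called genes among those named by the fixed rule 7 kept their call whichever library was left out: Serpinb1a, Star, Clu, Uchl1, Tspo, mt-Tf and Cxcl14. Called matrix genes went from 7 to 31 without control diet TAC 3 and to 2 without BCAA-free sham 2. Called cell cycle genes went from 4 to 19 without control diet TAC 3, and none were left without control diet TAC 2, control diet sham 1 or 2, BCAA-free TAC 2 or 3 or BCAA-free sham 1 or 2. Branched-chain amino acid breakdown went from 1 to 20 without control diet TAC 3, and in the other fits none were left except without BCAA-free TAC 1. Hypertrophic marker genes went from 2 to 1 in all fits but those without control diet TAC 1 or TAC 3.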

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

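The tests of a single scale, of the share of cardiomyocytes, of the diet effect in TAC hearts with a covariate and of other splits of the libraries were chosen only after the result was seen. The outlier test needs groups of at least 4 and was not run, and no deposited sample column was left unused. The results given here stand out because a test of the difference itself, over all 12 libraries, found that the response to TAC differed between the diets.

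A lower response on the BCAA-free diet was found for 19 genes that the fixed rule names in any comparison, with log2 differences of -3.28 for Sprr1a, -2.99 for Cthrc1, -2.69 for Col9a2, -2.58 for Serpinb1a, -2.32 for Mxd3, -2.18 for Lox, -2.14 for Thbs4, -1.46 for Star, -1.38 for Mt2, -1.32 for Clu, -1.32 for Lgals3, -1.27 for Uchl1, -1.21 for Mfap5, -1.12 for Mcm5, -1.05 for Fkbp5, -1.02 for Gpx3, -0.98 for Tspo, -0.92 for Fhl1 and -0.76 for Mcm6. Positive differences were found for 7: Bckdha (0.53), the clock repressor Cry1 (0.78), Ogdhl (0.86), Cdkn1c (0.96), Hmcn2 (1.29), Cxcl14 (1.29) and mt-Tf (1.74). Of these 26 genes 9 kept their call in every fit with a library left out: Clu, Cxcl14, Lox, Serpinb1a, Star, Thbs4, Tspo, Uchl1 and mt-Tf. On the control diet 8 calls were lost without TAC 1, 11 without TAC 2, none without TAC 3, 10 without sham 1, 13 without sham 2 and 12 without sham 3. On the BCAA-free diet 3 were lost without TAC 1, 15 without TAC 2, 15 without TAC 3, 12 without sham 1, 17 without sham 2 and 5 without sham 3. The highest adjusted p among the lost calls was 0.154.

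Camera called 16 lists for the difference. Negative medians were those of extracellular matrix (-1.10), cell cycle (-0.97), oxidative stress genes (-0.42), macrophage markers (-0.41), hypertrophic marker genes (-0.40), inflammatory genes (-0.38), glucocorticoid-responsive genes (-0.32), the unfolded protein response (-0.25), the interferon response (-0.24) and the amino acid response (-0.23). Positive medians were those of calcium handling (0.26), branched-chain amino acid breakdown (0.30), fatty acid oxidation (0.31), oxidative phosphorylation (0.31), the tricarboxylic acid cycle (0.32) and cardiomyocyte markers (0.42). With an estimated correlation none had an adjusted p below 0.22, and 5 lists had an unadjusted p under 0.05. Not called were the amino acid response without control diet sham 1 (adjusted p = 0.0531) and the inflammatory list without control diet TAC 2 (0.0508) or BCAA-free sham 3 (0.0622). The interferon list was not called without control diet TAC 2 (0.0796), control diet sham 2 (0.334) or BCAA-free sham 3 (0.088).

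The first pattern weighed is the smaller response to TAC on the BCAA-free diet. A single scale for all responses predicts 1 slope in every list. Of the matrix, cell cycle and hypertrophic marker slopes, the highest (hypertrophic marker) and lowest (cell cycle) differed by 0.469 ± 0.131 (SE over 2000 bootstrap draws of genes). With a library left out this difference was 0.385 to 0.573. A lower share of cardiomyocytes alone in control diet TAC hearts predicts like rises of other cell types. Macrophage and endothelial medians differed by 0.857 ± 0.141 (SE over draws of genes), against that share as the only change. Both SE treat genes as independent and do not measure the spread between samples. A lower share beside a gain of macrophages stays open. Cardiomyocyte markers had medians of -0.25 with TAC on the control diet (camera adjusted p = 0.406) and 0.25 on the BCAA-free diet (7.59e-05). With 1 slope on Rn7sk, Rmrp and Rpph1 for all groups in the model, most of the diet effect on the 40 matrix genes in TAC hearts stayed. Their median went from -1.75 to -1.65, their list mean from -1.78 ± 0.238 to -1.74 ± 0.279 and their calls from 39 to 38. Trends that differ between groups cannot be described by 1 slope. Col1a1 was at 19860 normalized reads in control diet TAC 3, high in these RNAs, against 45062.5 and 42823 in TAC 1 and 2. In BCAA-free TAC 1 and 3, also high, Col1a1 was at 7200 and 8392, against 4201 in TAC 2. A common trend therefore did not account for the whole effect, and trends that differ between groups stay open. The common trend stays open for the difference of responses, where the matrix median went from -1.11 to -0.97 and the list mean from -1.17 ± 0.336 to -1.10 ± 0.408. Calls of all genes went from 113 to 39 there, with a wider SE. The prediction written before, a median above 0.5 times its size, was met by more than 1 but less than 2 SE, a margin set after the value was seen. A smaller response to the same load, a smaller load or a slower course on this diet may each account for the pattern, and pressure gradients and heart weights were not used here.

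Other splits of the same libraries gave fewer genes in most cases. For TAC on the control diet the real split called 2710 genes and the highest other split 0, for TAC on the BCAA-free diet 1360 and 0, for diet in sham hearts 633 and 0, and for diet in TAC hearts 3025 and 0. In each of these only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the difference of responses, with joint size factors, 3 of 100 splits gave as many as the real 113, the real one included, and the highest other gave 1741. Both larger splits kept the 3 control diet TAC libraries together, and why they gave more genes was not tested. These splits also break up the effects of diet and of TAC, so they do not test the difference of responses alone and exclude nothing about it.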

How the results depend on the processing

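Settings with a covariate, joint size factors or several libraries omitted were chosen after seeing the data. Counts are given where they moved by more than 1.5 times from 2710 for TAC on the control diet, 1360 for TAC on the BCAA-free diet, 633 for diet in sham hearts, 3025 for diet in TAC hearts and 118 for the difference of TAC responses. Without the intensity trend limma called 1692, 0 (3431 at an unadjusted p under 0.05, 1424 by edgeR and 1893 by DESeq2), 0 (3041 at an unadjusted p under 0.05, 708 by edgeR and 1523 by DESeq2), 1868 and 1 in that order. With all 12 libraries in a single fit it called 4375 genes for TAC on the control diet, 302 for TAC on the BCAA-free diet and 150 for diet in sham hearts. With a 2-fold threshold 959, 112, 57, 953 and 56 genes remained in that order, a loss from the stricter rule itself. DESeq2 called 1523 for diet in sham hearts and 824 for the difference, and quantile normalization gave 179 for the difference. Elsewhere the cause was not tested.

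The replicate numbers did not pair the samples: 12 correlations between samples of the same number ran from -0.322 to 0.0414, and 0 were best with their own number. The block on that number, which spends degrees of freedom, gave 623 for TAC on the BCAA-free diet, 276 for diet in sham hearts and 50 for the difference. The covariate of Rn7sk, Rmrp and Rpph1 gave 0 for TAC on the BCAA-free diet by limma (1715 at an unadjusted p under 0.05; edgeR and DESeq2 were not run with it), 1120 for diet in sham hearts, 1443 for diet in TAC hearts and 40 for the difference. The covariate of atrial genes gave 1730 for TAC on the control diet, 5 for TAC on the BCAA-free diet, 1983 for diet in TAC hearts and 61 for the difference. On the BCAA-free diet both covariates went with TAC, so the 0 and 5 calls cannot separate them from it. Leaving out the 3 libraries highest in Rn7sk gave 1384, 297, 1071, 535 and 8 in the order above; it left 1 BCAA-free TAC library, assumed to vary like the other groups.

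With single libraries left out, counts ran from 1354 (control diet sham 3) to 4678 (control diet TAC 3), from 546 (BCAA-free sham 3) to 1257 (BCAA-free TAC 2), from 50 (BCAA-free sham 1) to 1071 (control diet sham 2), from 1195 (BCAA-free TAC 2) to 6025 (control diet TAC 3), and for the difference from 16 (BCAA-free sham 2) to 1755 (control diet TAC 3). Other alternatives stayed within 1.5 times.

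Camera called 18, 20, 20, 18 and 16 lists, and with the estimated correlation 0 in each comparison (4, 2, 6, 4 and 5 at an unadjusted p under 0.05, with the lowest adjusted p at 0.0649, 0.327, 0.199, 0.303 and 0.22). Fry called 9, 6, 6, 15 and 6. The correlation of both TAC responses across genes, 0.534, was 0.644 with a mean of at least 50 and 0.458 to 0.567 with single libraries left out. Of 9252 values of named genes under alternatives 8010 kept their side of the threshold, 69 of them with another sign while not past it, 1116 fell below it, 125 rose past it and 1 changed direction: Gapdh with TAC on the BCAA-free diet, 0.25 by the values as deposited and -0.11 with quantile normalization. Called members moved by more than 1.5 times with a library left out in 20 of 29 lists with any for TAC on the control diet, 20 of 26 for TAC on the BCAA-free diet, 19 of 19 for diet in sham hearts, 23 of 30 for diet in TAC hearts and 9 of 9 for the difference. Counting error was not separated out, as stated above, and the folds of genes such as Cyp1a1 rest on few reads.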

Other observations

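The tests of clock phase, of TAC on the clock genes and of diet or surgery on the structured RNAs were chosen only after the result was seen, and those of poly(A) tails and of aryl hydrocarbon receptor targets were written before. In sham hearts Gnmt, which uses up methyl groups from methionine, was higher by 1.06, a call lost without BCAA-free sham 1 (adjusted p = 0.0831), BCAA-free sham 3 (0.0578) or control diet sham 3 (0.0535).

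The next pattern weighed is the level of Rn7sk, Rmrp and Rpph1, which differed between libraries of 1 group by up to 56.2 times in control diet sham, 9.77 times in BCAA-free TAC, 5.03 times in control diet TAC and 1.29 times in BCAA-free sham. Ratios above 3 within 3 groups exclude diet or surgery as the whole cause. RNA without poly(A) tails kept in these libraries stays open, as its classes parted: genes at ribosomal RNA loci took 3.12% of reads in control diet sham 2, 2.06% in BCAA-free TAC 1 and 2.31% in BCAA-free TAC 3, which is 7.97 times the mean of the other control diet sham libraries, and 2.4 and 2.69 times the share in BCAA-free TAC 2. The medians of 82 small nuclear and nucleolar RNAs were higher there by only 0.30, 0.32 and 0.01 in log2 units, and those of 23 replication-dependent histones differed by -0.05, 0.02 and -0.07, the lowest at -0.0726. The bound of 0.5 set in advance on either class was therefore met, but it left out the ribosomal class, whose values were taken up after they were seen and go the other way.

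The last pattern weighed is the spread of clock genes within groups. Arntl ran from 309.8 to 2159 normalized reads in control diet sham hearts. Across the 12 libraries, centred within groups, the mean of Arntl and Npas2 went against that of Dbp, Nr1d1, Nr1d2, Per3 and Tef, with a Pearson r of -0.862 (two-sided exact permutation p = 0.0162 over 1296 permutations within groups) and a Spearman rho of -0.713 (permutation p = 0.0262). Without the 2 libraries farthest from the median, control diet sham 1 and 2, r was -0.444, so the relation rests on those samples; hearts taken at different clock phases may account for it. With TAC, Arntl changed by -1.01 ± 0.145 on the BCAA-free diet (adjusted p = 0.00181) and by -1.16 ± 0.800 on the control diet (adjusted p = 0.396), where the spread between libraries leaves an effect of TAC open.

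Cyp1a1 was higher on the BCAA-free diet in TAC hearts (4.49) and in sham hearts (2.30). The latter call was lost without BCAA-free sham 1, 2 or 3 or control diet sham 3. Cyp1a1 was lower with TAC on the control diet (-2.51 ± 0.457, adjusted p = 0.00783, chosen after its values were seen) at a mean of 17.9 normalized reads. A hypothesis was that the aryl hydrocarbon receptor, which drives Cyp1a1, was more active on that diet and raised its other targets. Of Ahrr, Tiparp, Cyp1b1, Nqo1 and Aldh3a1, 0 of 5 were called higher by limma in TAC hearts, 0 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2. Uncalled there were Ahrr (0.42), Aldh3a1 (0.28), Cyp1b1 (-0.25) and Nqo1 (-0.35). Tiparp was lower, at -0.45 (adjusted p = 0.0428). This call was lost without BCAA-free TAC 2 (adjusted p = 0.192) or 3 (0.138) or control diet TAC 1 (0.0937) or 2 (0.105). In sham hearts Cyp1b1 was higher, at 0.56 (adjusted p = 0.0202), a call lost without BCAA-free sham 1 (adjusted p = 0.0979), sham 2 (0.0761) or sham 3 (0.0696) or control diet sham 3 (0.0698). A rise of these targets together with Cyp1a1 was therefore not found in TAC hearts. In sham hearts, not the test set in advance, all 5 had positive changes. Ahrr (0.33, adjusted p = 0.173), Tiparp (0.20, 0.730), Nqo1 (0.23, 0.605) and Aldh3a1 (0.60, 0.408) did not pass.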
